A study of Mus musculus with 7 samples.

How the data were processed

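The data are polyA RNA-seq profiles of a clonal, stable line of B16, a mouse melanoma of C57BL/6 origin. Per the labels' protocols, detached cells were held for 5 h with 10 nM recombinant mouse interferon gamma (IFNγ) or with medium alone (mock), washed 3 times and seeded in duplicate at 35000 cells per well of a 96-well plate. RNA was taken at labelled times of 0 (T0), 23.5, 48 and 91 h. The 7 samples form 7 groups: T0, and the IFNγ and mock groups at each of the 3 later times. The labels do not say from which moment the hours were counted, nor whether the T0 cells had been through a pulse.

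The files are 6 tables, each comparing T0 with 1 of the other groups. Per the submitters' processing notes, the tools were STAR 2.5.0a, Picard 1.124, HTSeq 0.5.3 and DESeq (version not given), on builds mm10 and GRCm38. The annotation, the strand setting, the treatment of reads that match several places and the filter that decided which genes were listed are not given in the sources used here. Each table holds, per the file headers, the authors' mean signal per gene for T0 and for the other group, a value that behaves as reads divided by a size factor per library. The deposited log2 column is the log2 of the T0 mean over the mean of the other group. The deposited p-value columns are the authors' DESeq p and adjusted p. The tables list between 12905 and 13321 genes, and 13587 genes occur in at least 1. A gene missing from a table has no value there, and is described as not listed. In 5 of the tables, 4 entries name no gene (unaligned, ambiguous, multiply aligned and unassigned reads). They make up 57.1% to 70.3% of the listed total of the group, and 63.9% in T0, and were left out of all totals and tests. A symbol was taken from the reference annotation for 19 genes, and 6 gene identifiers share a symbol with another. No value column was left unused (0).

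The labels name 1 sample per group, but each deposited mean is a sum of whole multiples of 2 steps, as a mean over 2 libraries of whole reads is. The read numbers of both libraries were therefore solved from the means by testing every whole-number pair. A pair was accepted within 1.2 times the rounding error of the 10 digits printed, and for levels of 3000 or more only where the library values lay within a log2 ratio of 2 of each other. Of 157076 values in 12 columns, 156378 (99.6%) gave exactly 1 pair, 104 gave none and 594 gave more than 1. Those without a single solution, mostly genes of very high level such as Actb, Dct and Pmel, were left out of tests and keep only the authors' mean. Size factors computed afresh from the recovered reads lay within 0.612% of those the means imply. On simulated means the same procedure solved 99.8% of 91890 values uniquely, with 0 wrong. The simulated reads were drawn around genes already solved, so this cannot show errors where the window of a log2 ratio of 2 is false. That limit matters most for IFNγ at 48 h, where genes below 3000 lay further apart (Zbp1 at 768 and 4310). Library 1 is the one with the larger size factor. That number only names a library, so no library of one group is paired with one of another. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Depth in recovered genes ran from 13017187 to 24459375 reads per library.

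The IFNγ and mock groups stand in different tables, normalised separately by the authors. Their libraries were put on 1 scale through T0, which all 6 tables share, and every comparison of IFNγ with mock below rests on that step. Levels are the authors' means on that scale, called normalised reads, and SDs are over the 2 recovered libraries. The log2 ratio of a gene is log2 of (IFNγ level + 1) over (mock level + 1). The pseudocount of 1 understates the change of genes of low level. Genes with a level of at least 20 in either group were compared. limma 3.58.1 in R 4.3.3, with a trend of the variance with level, was fitted to log2(normalised reads + 1) of the 4 libraries of each time, with Benjamini-Hochberg adjustment, two-sided. All adjusted p-values and standard errors (SE) below are limma's unless they are named as the authors'. The SE and p of a gene belong to limma's estimate, the difference of mean log2 values. That estimate can differ from the printed log2 ratio of the means where the libraries of a group lie far apart. "Higher" and "lower" by limma mean an adjusted p under 0.05 at any fold. The rule of size asks for a 2-fold difference of the group means and a level of at least 20. "Called" means that both were met. The difference between times was tested in limma as an interaction over 8 libraries. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

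The comparisons, the rule of size, the limma test for the case of replicates, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The solving of libraries, the limma test of the difference between times, the combination of limma with the rule of size, the fit over all 14 libraries, the fit without a variance trend and the removal of libraries from results other than the gene counts were chosen after the structure of the tables had been seen. The rule names, for each time, the 15 highest and 10 lowest log2 ratios past the rule of size, a fixed set of 20 genes, 1 of which is not reported here (Irf1, Socs1, Cd274, H2-K1, H2-D1, B2m, Tap1, Psmb8, Psmb9, Nlrc5, Ciita, Cd74, Cxcl9, Cxcl10, Gbp2, Irgm1, Ido1, Ifngr1 and Ifngr2), and up to 4 members of a described list, those past the rule of size or else those of highest level. Against T0 it names the 8 highest and 8 lowest genes past the rule of size at all times, and for the difference between times the 8 largest and 8 smallest. Symbols of predicted models are counted but not named. Genes named beyond the rule are said to have been chosen after their values were seen.

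The 30 lists hold 598 genes, of which 20 are in more than 1 list and 480 are listed in any table. They cover IFNγ signalling, interferon-inducible GTPases, MHC class I and class II presentation, chemokines, immune checkpoint genes, type 1 interferon-stimulated genes, interferon genes and receptors, cell death, pigment cell differentiation, dedifferentiation, S phase, G2/M, hypoxia and glycolysis, the integrated stress response, sterol synthesis, immediate early genes, p53 targets, phosphatidylserine handling, NF-κB targets, complement, tryptophan and arginine metabolism, ribosomal proteins, mitochondrial transcripts and control genes, with markers of T cells, myeloid cells, fibroblasts, endothelium and keratinocytes. For each, the measured members were counted, and counted again with p adjusted over the list alone. A measured gene whose libraries could not be solved was not tested by limma and counts there as not passing. Lists were tested with limma's camera at its preset correlation, with camera at an estimated correlation and with limma's fry, and placed among 10000 random lists of matched level (20 bins, seed 1). Fry asks whether a list changed, without comparing it with other genes. With camera's estimated correlation no list passed for IFNγ against mock or for mock against T0 at any time. The smallest adjusted p for IFNγ against mock was then 0.159 at 23.5 h, 0.524 at 48 h and 0.178 at 91 h. For the GTPase, class I and type 1 interferon-stimulated lists in turn, fry's adjusted p was 0.0035, 0.0035 and 0.0057 at 23.5 h. It was 0.018, 0.018 and 0.020 at 91 h, and 0.275 for each at 48 h. Against T0, fry passed none of these lists in mock at 23.5 h and all at 48 and 91 h (adjusted p at most 0.0082). At its preset correlation, which takes a list's genes as nearly independent, camera passed these lists for IFNγ against mock at each time (adjusted p at most 2.8e-21).

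limma was tested on simulated reads with 200 genes changed, 50 per fold. At 23.5 h (12452 genes) it called 90%, 94%, 100% and 100% of genes changed 1.5, 2, 4 and 8-fold, and 3 unchanged genes. At 91 h (12434 genes) the shares were 72%, 94%, 100% and 100%, with 3 unchanged genes. At 48 h (12652 genes) they were 4%, 30%, 86% and 94%, with 0 unchanged genes. With no gene changed it called 0 at each time. The simulation drew the spread of each gene at random from genes of similar level. Simulated genes thus had no spread of their own and did not vary together. In the data some lists did, such as the GTPase list at 23.5 h (estimated correlation 0.86). The shares at each time therefore hold only for genes like the simulated ones. In the data of 48 h the spread was large in the GTPase and antigen presentation genes themselves (Psmb8 at 630.9 and 2905 in the 2 IFNγ libraries). The shares at 48 h therefore do not apply to such genes, and 0 calls there do not mean that large changes were absent. Alternatives were other pseudocounts (5 and 0.1), level minimums (none and 100), folds (1.5 and 4), scales (median log2 ratio set to 0, or equal totals of recovered genes), references (T0, or the mean of the 3 mock groups), an exact binomial test on summed reads, which compares libraries and not conditions, a stricter threshold on the authors' adjusted p (0.01), unmatched random lists, and each library left out. The 2 other scales moved the median of all genes by at most 0.04 (log2) in any IFNγ and mock comparison. Genes with close paralogs or overlapping neighbours (H2 class I, Gbp, Irg and Tgtp families, Apol9a and Apol9b, histone and Rny genes) are uncertain, since how shared reads were counted is not stated. Coordinates are GRCm38 from GENCODE vM21, 1-based.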

Results

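Gene expression of B16 melanoma cells was profiled over several times to ask whether a passing exposure to IFNγ, a cytokine of T and NK cells, is followed by a lasting response. The values rest on 14 libraries, 2 per group. Depth is given as reads in recovered genes. The T0 libraries held 24459375 and 20748029 reads. In the IFNγ groups the libraries held 20007382 and 19903769 reads at 23.5 h, 23223947 and 17520539 at 48 h, and 16011308 and 14380552 at 91 h. In the mock groups they held 18245415 and 17892104, then 19298224 and 16532604, then 16556582 and 13017187. Over genes of at least 1000 normalised reads, the log2 ratio of the 2 libraries of a group had an SD of 0.0672 in T0, 0.0667, 0.419 and 0.0870 in the IFNγ groups at 23.5, 48 and 91 h, and 0.0958, 0.150 and 0.0874 in the mock groups. The IFNγ libraries at 48 h differed 2-fold or more in 121 of 4894 such genes, and 0 genes did so in each other group. Genes without a single solution, such as Cd74 and H2-T23 with IFNγ at 48 h, are not in these figures. The share of an 18S ribosomal RNA entry (Rn18s-rs5) in the gene total was 9.47%, 9.77% and 11.8% in the IFNγ groups, 12.4%, 12.7% and 14.2% in the mock groups and 12.5% in T0.

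**Figure D1:**
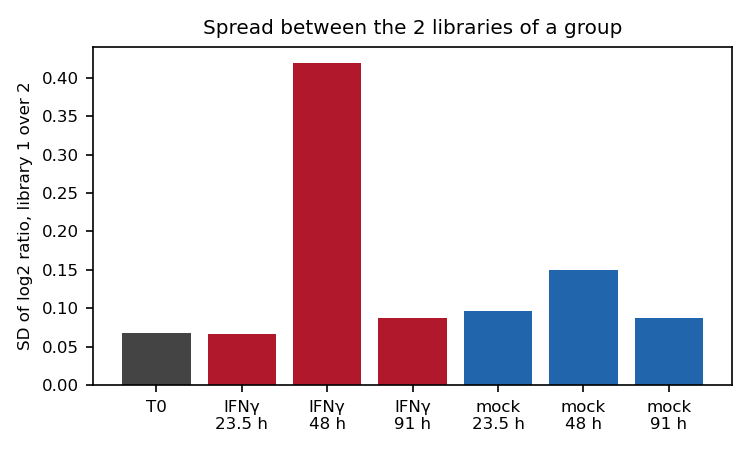
Bars give the SD, over genes of at least 1000 normalised reads, of the log2 ratio of the 2 recovered libraries in each of the 7 groups. The IFNγ group at 48 h stands at 0.419, and the next highest, the mock group at 48 h, at 0.150.

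Markers of other cell types were scarce. Of 13 T cell markers 2 were listed in any table, with Lck highest at 143 normalised reads, and of 13 myeloid markers 2, with Cd68 highest at 97.1. Among 10 fibroblast markers 6 were listed (Pdgfrb highest, 254), among 8 endothelial markers 1 (Vwf, 933), and among 8 keratinocyte markers 0.

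At 23.5 h after the labelled start, cells that had met IFNγ held far more transcripts of interferon-inducible GTPases, which act on vacuoles of intracellular pathogens, and of the MHC class I pathway than mock cells. Igtp stood at 6304 ± 67.1 against 59.2 ± 3.34 normalised reads (SD, n = 2 libraries each; log2 ratio 6.71, SE 0.07, limma adjusted p = 2.4e-14), and Iigp1 at 6583 ± 32.6 against 18.7 ± 4.32 (8.38, SE 0.12, limma adjusted p = 6.3e-13). Nlrc5, the transactivator of class I genes, stood at 2429 ± 0.229 against 23.1 ± 6.26 (6.66, SE 0.15, limma adjusted p = 1.9e-11). Irf1, a transcription factor of the IFNγ response, rose by 2.46 (SE 0.06, 2673 ± 72.8 against 486 ± 36.6, limma adjusted p = 5.2e-11). Socs1, a feedback inhibitor of the pathway, rose by 1.69 (SE 0.23), and Cd274, which encodes PD-L1, by 1.80 (SE 0.09).

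The other genes with the highest ratios were Apol9a (6.69) and Apol9b (6.18), the complement gene C4b (5.42), Ifi47 (5.17), Irgm2 (5.04), Oasl2 (4.95), Gbp2 (4.85), H2-T23 (4.82), the peptide transporter genes Tap1 (4.74) and Tap2 (4.23), Gbp3 (4.49) and Gbp7 (4.17), all called. H2-K1 rose by 3.89, H2-D1 by 3.30, B2m, the shared light chain of class I molecules, by 2.83, and Irgm1 by 3.76. Cxcl10, a T cell attracting chemokine, was high in both groups, at 7312 ± 218 with IFNγ and 6139 ± 263 with mock (0.25, SE 0.05, limma adjusted p = 0.0033). The receptor genes Ifngr1 (-0.04, limma adjusted p = 0.785) and Ifngr2 (-0.12, limma adjusted p = 0.161) did not pass. Cxcl9 and Ido1 were not listed in any table. Nlrc5 (ENSMUSG00000074151, protein coding) lies on chromosome 8 from 94434356 to 94527272, Igtp on chromosome 11 from 58199556 to 58207591, and Irf1 on the same chromosome from 53770014 to 53778374.

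Genes of antigen presentation on class II molecules were in part listed only for IFNγ at this time, so that no mock value exists. Cd74, the invariant chain, stood at 2716 against 1.91 in T0. Ciita, the class II transactivator, was listed at 186, H2-Aa at 982, H2-Eb1 at 578 and H2-Ab1 at 521, and Ciita and H2-Eb1 were listed at 0 in T0. The immunoproteasome genes Psmb8 (1410) and Psmb9 (1739) and the GTPase genes Tgtp1 (2891) and Gbp4 (866) were likewise without a mock value. In all, 162 genes were listed only for IFNγ at 23.5 h, 49 of them past the rule of size over T0, and these stand outside the counts that follow. At 48 h the same held for 207 genes (45 past the rule) and at 91 h for 128 (33 past it).

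By group, all 8 measured GTPase genes were called higher (8 adjusted over the list alone, median log2 ratio 4.94), as were 16 of 20 class I presentation genes (18 higher by limma, 18 adjusted over the list alone, median 2.96) and 39 of 42 type 1 interferon-stimulated genes (42 higher by limma, 42 adjusted over the list alone). Camera's adjusted p = 0.159 with an estimated correlation for each of the 3. Among 17 IFNγ signalling genes 7 rose by limma (9 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), with Stat2 at 2.35 beside Irf1 and Socs1. The 1 measured class II gene, H2-DMb1, rose by 3.54. Of 8 checkpoint genes 5 rose (6 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation), led by Serpinb9, a granzyme B inhibitor, at 2.24. Of 6 complement genes 5 rose (5 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation), C1ra by 1.74 beside C4b, and C2 from 1009 in mock to 2324. Of 12 chemokine and cytokine genes 4 rose (5 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), among them Il18bp (2.89), a decoy for interleukin 18, and Il18 itself, at 73.4 against 33.2. Of 20 cell death genes 11 rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), led by Casp12 (3.58), the pyroptosis effector Gsdmd (1.79), Casp4 (1.49) and the necroptosis effector Mlkl (1.18).

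Smaller shifts ran through other groups. Of 30 G2/M genes 20 fell (25 adjusted over the list alone, median -0.19, adjusted p = 0.262 with an estimated correlation). Among them was Mki67 at 11448 ± 678 against 14761 ± 2635 (-0.37), with the mock libraries far apart at 12897.6 and 16624.5. Of 28 S phase genes 6 fell (8 adjusted over the list alone, median -0.07, adjusted p = 0.408 with an estimated correlation). Of 20 p53 targets 9 fell (10 adjusted over the list alone, median -0.17, adjusted p = 0.159 with an estimated correlation), of 11 NF-κB targets 5 (6 adjusted over the list alone, median -0.32, adjusted p = 0.241 with an estimated correlation), and of 34 ribosomal protein genes 12 (17 adjusted over the list alone, median -0.12, adjusted p = 0.262 with an estimated correlation). Of 18 pigment genes, 14 of them tested, 10 rose (11 adjusted over the list alone, median 0.29, adjusted p = 0.159 with an estimated correlation). Tyr, which encodes tyrosinase, stood at 13957 in mock and 16946 with IFNγ (0.28), and Mitf, the melanocyte master regulator, rose by 0.23. Of 24 sterol genes 10 rose (17 adjusted over the list alone, median 0.18, adjusted p = 0.426 with an estimated correlation). Mixed counts, higher and lower by limma, were 10 and 4 of 27 stress response genes (12 and 4 adjusted over the list alone), 5 and 3 of 22 immediate early genes (7 and 3 adjusted over the list alone), 4 and 2 of 15 dedifferentiation genes (5 and 2 adjusted over the list alone) and 3 and 3 of 30 hypoxia genes (3 and 3 adjusted over the list alone). Of 17 phosphatidylserine genes 3 rose (5 and 1 adjusted over the list alone), Plscr2, a scramblase family member, by 1.11. Control genes gave 2 and 1 of 16, 13 of them tested (2 and 1 adjusted over the list alone, median -0.07 and mean 0.12). Of 7 mitochondrial transcripts only 2 could be tested. By limma 1 of these fell, mt-Nd4 by 0.29, and 2 adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). Of 2 measured interferon receptor genes Ifnar2 rose by 0.32 (1 adjusted over the list alone). The 4 measured tryptophan and arginine metabolism genes had a median of -0.03. Of the markers of other cells, Lck (0.83) and Vwf (0.53) passed, Cd68 (0.24) did not, and of 6 fibroblast genes Acta2 rose by 1.66 and 1 fell (1 and 1 adjusted over the list alone, median -0.13 and mean 0.15).

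The lowest ratios belonged to genes of low level. Sorcs2 fell by 2.04 (11.7 ± 1.31 against 51.2 ± 6.69, SE 0.28, limma adjusted p = 4.8e-04), and the small RNA genes Rny1 and Rny3 by 1.87 and 1.79. Csdc2 (-1.58), Hist1h3g (-1.48), n-R5s193 (-1.46), Col2a1 (-1.42), Prr7 (-1.39), Hist1h4f (-1.37) and Hist1h4a (-1.36) followed. The Rny and replication-dependent histone transcripts lack the long polyA tail that the selection step binds. The 18S ribosomal RNA entry also held a smaller share with IFNγ (9.47%) than with mock (12.4%) at 23.5 h. Whether the libraries differed in that step was not tested.

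Of 12452 genes tested at 23.5 h, limma found 1065 higher and 755 lower, and 144 and 43 were called. Without a variance trend limma found 295 and 85, and in 1 fit over all 14 libraries 242 and 77, with 12 called lower in each. With equal totals of recovered genes in place of the T0 scale the split became 902 higher and 1004 lower, 47.3% higher against 58.5%. Without IFNγ library 1 limma found 602 and 398, and without IFNγ library 2 it found 604 and 419; the called lower genes then numbered 23 and 89, and 27 without mock library 1.

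At 48 h the means of GTPase and antigen presentation genes stood apart between the groups, but the IFNγ libraries differed so much from each other that no gene passed limma. Nlrc5 stood at 2468 ± 1189 against 113 ± 18.8 (SD, n = 2; log2 ratio 4.43, SE 0.35, limma adjusted p = 0.115), Psmb8 at 1768 ± 1608 against 46.8 ± 13.6 (5.21, SE 0.72, limma adjusted p = 0.285) and Iigp1 at 9603 ± 6668 against 489 ± 103 (4.29, SE 0.51). Cd74 had the highest ratio, 6.41, from 12947 against 152, but its reads could not be assigned to libraries and it was not tested.

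Further ratios at 48 h were 4.90 for Zbp1, 4.61 for H2-DMa, 4.53 for Gbp9, 4.49 for Psmb9, 4.33 for Il18bp, 4.12 for Ifi204, 4.02 for H2-T23, 3.92 for Tgtp2, 3.88 for C4b, 3.81 for H2-DMb1 and 3.57 for Apol9b, whose limma adjusted p = 0.106 was the smallest of all. In each of these that could be assigned to libraries IFNγ library 2 was the higher. Libraries 1 and 2 stood at 54.6 and 857 for H2-DMa, 54.6 and 500.5 for Il18bp, 189 and 1241 for H2-DMb1 and 768 and 4309.8 for Zbp1. For these genes limma's estimates were 3.55, 3.60, 3.26 and 4.46 in turn, below the ratios of the means. H2-D1 stood at 2.82, H2-K1 at 2.70, Gbp2 at 2.47, Tap1 at 2.30, B2m at 2.06 (not tested), Irgm1 at 1.69, Socs1 at 1.18, Cd274 at 1.10, Irf1 at 1.02, Ifngr1 at -0.16, Ifngr2 at -0.25 and Cxcl10 at -0.29. Ciita (248), H2-Aa (2828), H2-Ab1 (1346), H2-Eb1 (1114), Tgtp1 (3668), Gbp4 (2563) and Gbp10 (683) were listed only for IFNγ. The lowest ratios were Sorcs2 (151 ± 172 against 607 ± 95.5), Cyp26b1 (-1.95), Tmem119 (-1.84), Kcnh2 (-1.72), Nedd9 (-1.65), Adam19 (-1.63), Mmp17 (-1.62), Car12 (-1.59), Rgs8 (-1.57) and Adam11 (-1.52).

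Adjusted over the list alone, 12 of 12 GTPase genes were higher at 48 h (median 2.43, camera's adjusted p = 0.524 with an estimated correlation). So were 16 of 23 class I genes, 21 of them tested (median 1.91, adjusted p = 0.535 with an estimated correlation). The same held for 30 of 45 type 1 interferon-stimulated genes (median 0.69, adjusted p = 0.524 with an estimated correlation). Of 3 class II genes 2 could be tested, and 2 were higher (adjusted p = 0.535 with an estimated correlation). The counts were 5 of 9 for checkpoint genes and 6 of 21 for cell death genes (adjusted p = 0.524 with an estimated correlation for each). Over all genes tested the count was 0 in each of these lists. Of markers of other cells Vwf, at 933 with IFNγ and 432 with mock (1.11), and Cd68, at 26.0 and 8.32 (1.53), were past the rule of size and higher adjusted over the list alone (1 of 1 endothelial and 1 of 2 myeloid genes). Acta2 (1.40) was past the rule of size alone, and Lck stood at 0.24; none of these passed limma over all genes tested. The 2 IFNγ libraries were far apart in genes of antigen presentation, at 630.9 and 2905 normalised reads for Psmb8, 16.4 and 479 for Ciita and 55.3 and 2173 for H2-Eb1, while Cxcl10 went the other way with 17455 and 6202.

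Of 12652 genes tested at 48 h, limma passed 0, with 847 at an unadjusted p under 0.05 (505 higher, 342 lower). The fit over all 14 libraries passed 680 and the exact binomial test of summed reads, which compares libraries, 6310. The rule of size alone took 173 higher and 67 lower genes, 390 and 245 without IFNγ library 1. In that case limma passed 1663 higher and 1622 lower genes and without IFNγ library 2 284 and 183, where the lone library is assumed to vary as the mock pair does; without mock library 1 or 2 it passed 5 and 4, all higher.

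**Figure D2:**
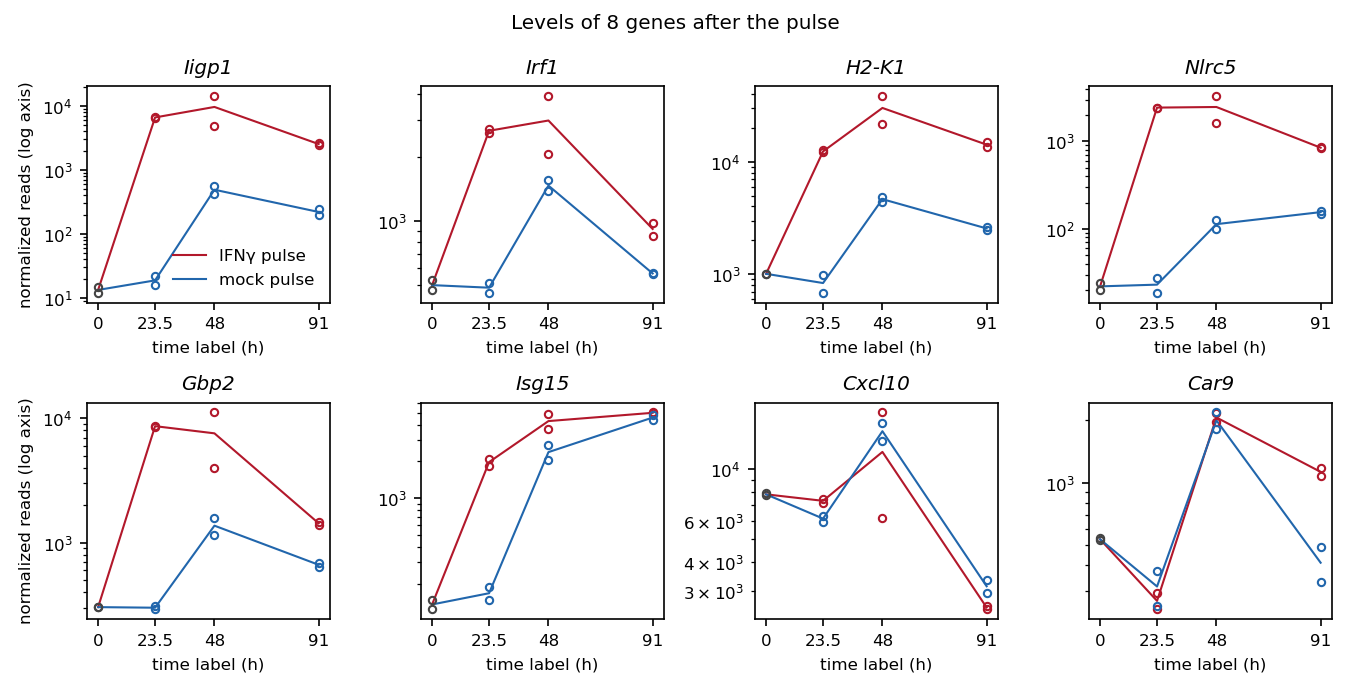
Normalised reads (log axis) of 8 genes by labelled time (h) in the IFNγ and mock groups, lines joining the authors' means and open circles giving the 2 recovered libraries. Isg15 in mock climbs from 167 at 23.5 h to 2383 at 48 h. Nlrc5 in mock climbs from 23.1 at 23.5 h to 155 at 91 h, against 846 with IFNγ at 91 h.

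At 91 h all 11 measured GTPase genes and 17 of 22 class I presentation genes were higher by limma in cells that had met IFNγ. The immunoproteasome gene Psmb9 stood at 393 ± 62.0 against 28.3 ± 7.62 (SD, n = 2 each; log2 ratio 3.75, SE 0.20, limma adjusted p = 4.8e-09), Psmb8 at 292 ± 12.2 against 42.8 ± 4.97 (2.74, SE 0.16, limma adjusted p = 1.7e-08), and Iigp1 at 2527 ± 118 against 219 ± 34.2 (3.52, SE 0.09, limma adjusted p = 1.3e-12). H2-K1, a class I heavy chain, stood at 14188 ± 1069 against 2550 ± 80.2 (2.48, SE 0.05, limma adjusted p = 2.4e-13) and Nlrc5 at 846 ± 23.6 against 155 ± 9.05 (2.44, SE 0.09). Irf1 was higher by 0.70 (SE 0.08, limma adjusted p = 2.2e-05). Cxcl10 was lower, at 2562 ± 61.4 against 3156 ± 280 (-0.30, SE 0.06, limma adjusted p = 0.0026).

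Also called were Gbp9 (3.17), the nucleic acid sensor gene Zbp1 (2.96), Tgtp2 (2.12), Gbp6 (2.12), H2-D1 (2.11), Apol9b (2.11), Apol9a (2.02), Tlr1 (1.98), Fhad1 (1.87), Cd74 (1.63), Tap1 (1.41), B2m (1.31) and Gbp2 (1.11). Aire, known for its role in thymic tolerance, stood at 313 ± 62.6 against 73.2 ± 49.4 (2.08, SE 0.31, limma adjusted p = 1.5e-04). In T0 it stood at 257, so the IFNγ level was near T0 and the mock level, with libraries at 38.2 and 108, below it. Irgm1 (0.70) and Cd274 (0.69) passed limma below 2-fold, and Socs1 (0.19), Ifngr1 (0.04) and Ifngr2 (0.12) did not pass. Gbp4 (255), Tgtp1 (253), H2-T10 (108), H2-Aa (58.1), Gbp5 (36.6) and H2-Eb1 (32.0) were listed only for IFNγ, and Ciita was not listed for either. Of markers of other cells the myeloid marker Cd68 was called higher with IFNγ, at 97.1 ± 13.9 against 35.0 ± 13.8 and 17.6 in T0 (1.44, SE 0.26, limma adjusted p = 9.9e-04). The fibroblast marker Col1a1 fell by 0.97 (limma adjusted p = 0.0229), and Lck (-0.16) and Vwf (0.22) did not pass. Psmb9 lies on chromosome 17 from 34181987 to 34187764, Tap1 from 34187553 to 34197225, Psmb8 from 34197721 to 34201454 and H2-K1 from 33996017 to 34000347 of the same chromosome; the first pair overlap by annotation, so reads of one can be counted for the other.

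Of 11 GTPase genes 11 were higher by limma (11 adjusted over the list alone, median 1.48), of 22 class I genes 17, of which 12 called (20 adjusted over the list alone) and of 2 class II genes 2 (2 adjusted over the list alone), each with camera's adjusted p = 0.178 with an estimated correlation. Of 44 type 1 interferon-stimulated genes 34 were higher by limma (39 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), but their median was 0.38 and 2 were called, Zbp1 and Oasl2 (1.52), an inhibitor of viral replication. Pigment genes were higher in 11 of 18, 14 of them tested (13 adjusted over the list alone, median 0.25, adjusted p = 0.178 with an estimated correlation). IFNγ signalling genes were higher in 4 of 17 (4 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation). Checkpoint genes were higher in 4 of 7 (4 adjusted over the list alone, adjusted p = 0.277 with an estimated correlation).

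Hypoxia and glycolysis genes, among which 3 were higher and 3 lower at 23.5 h, were mostly higher with IFNγ at 91 h. Of 30 such genes 23 were higher and 2 lower by limma (24 and 3 adjusted over the list alone, median 0.73, adjusted p = 0.301 with an estimated correlation). The called members with the largest ratios were Ankrd37 (1.68), Car9 (1.45), a carbonic anhydrase induced by hypoxia, Bnip3 (1.42), a mitophagy receptor, and Adm (1.31). Car9 stood at 1125 with IFNγ and 412 with mock (SE 0.13, limma adjusted p = 1.3e-06), and Bnip3 at 2705 and 1008 (SE 0.11, limma adjusted p = 5.7e-07). Pdk1, which encodes a pyruvate dehydrogenase kinase, was higher by 1.27 and the glycolytic gene Tpi1 by 1.02, while Car12, another carbonic anhydrase gene, fell by 1.05. For the difference of the ratio between 91 and 23.5 h the list had a median of 0.72 (adjusted p = 0.253 with an estimated correlation). Car9 lies on chromosome 4 from 43506966 to 43513729.

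Lower groups at 91 h were p53 targets (14 of 20 by limma, 16 adjusted over the list alone with 1 higher, median -0.32, adjusted p = 0.178 with an estimated correlation), among them Ccng1 (-0.18) and the DNA damage gene Gadd45a (-0.64, chosen after its values were seen), the integrated stress response (13 of 27 lower and 1 higher, 14 and 2 adjusted over the list alone, median -0.15, adjusted p = 0.178 with an estimated correlation) and S phase genes (10 of 28, 12 adjusted over the list alone, median -0.28, adjusted p = 0.412 with an estimated correlation). Among immediate early genes 2 of 25 were higher and 7 lower (3 and 8 adjusted over the list alone). Control genes gave 5 higher and 2 lower of 16 (6 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.302 with an estimated correlation), with the glycolytic genes Gapdh (0.79) and Pgk1 (0.74) among the higher.

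The lowest ratio at 91 h was that of Il17f (-4.88), listed at 0 with IFNγ and at 28.4 ± 40.2 with mock, which did not pass (limma adjusted p = 0.173). Next came Nrk (-1.77), Fam131b (-1.72, 30.8 ± 0.111 against 103 ± 2.65, SE 0.21, limma adjusted p = 4.6e-05), Sgms2 (-1.54), Cpz (-1.52), Sorcs2 (-1.40), Arhgef28 (-1.37), Arhgef16 (-1.26), Prkg2 (-1.25) and Kcnh2 (-1.22), all called.

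Of 12434 genes tested at 91 h, limma found 1088 higher and 937 lower, and 70 and 23 were called. Without a variance trend limma found 71 and 36 (41 and 7 called), and in 1 fit over all 14 libraries 92 and 67 (29 and 5 called). With equal totals of recovered genes the split became 945 higher and 1083 lower, 46.6% higher against 53.7%. Without IFNγ library 1 the limma counts were 497 and 421 and without IFNγ library 2 694 higher; without mock library 1 the called lower genes numbered 45.

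**Figure D3:**
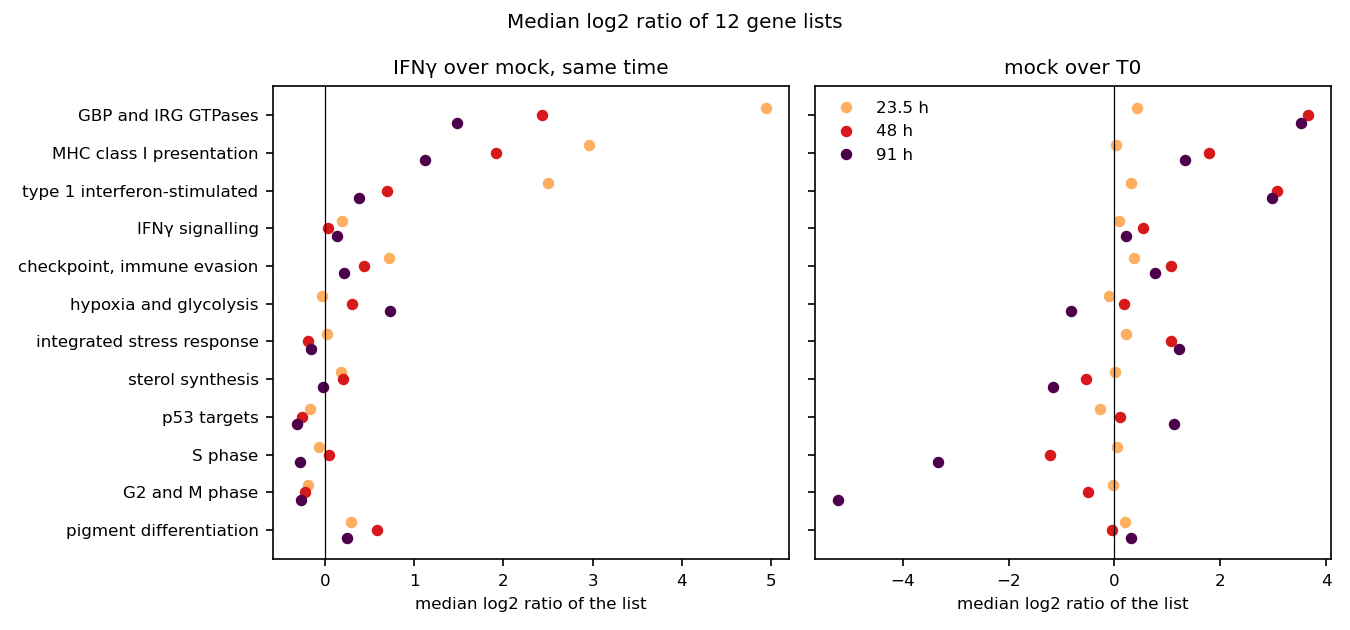
Median log2 ratios of 12 gene lists by labelled time (h), for IFNγ over mock and for mock over T0. The GTPase list falls from 4.94 to 2.43 and 1.48 in the first, over 8, 12 and 11 measured genes, so these medians are not of the same genes. The type 1 interferon list rises from 0.32 to 3.06 and 2.98 in the second.

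How far the early difference lasted was counted by the rule of size. Of the 144 genes higher at 23.5 h, with a median log2 ratio of 2.14, 71 (49.3%) were past the rule at 48 h (median 1.02, 142 above 0) and 21 (14.6%) at 91 h (median 0.44, 133 above 0). Without IFNγ library 2 of 48 h the share of these higher genes past the rule at 48 h was 29.1% in place of 49.3%. Lists of these sizes drawn independently would share 1.51 and 0.653 genes. By limma 96 of the 144 were higher at 91 h. Their level over T0 had a median log2 of 2.43, 3.01 and 2.57 at 23.5, 48 and 91 h with IFNγ, and of 0.24, 2.08 and 1.95 with mock, so that the mock group drew nearer while the IFNγ group stayed above T0. Of 51 lower genes (33 and 116 without IFNγ library 1 and 2 of 23.5 h) 17 (33.3%) were past the rule at 48 h and 2 of the 48 still listed (4.17%) at 91 h. Of genes selected as higher at 48 h, 40 of 156 (25.6%) were past the rule at 91 h. Genes without a mock value at 23.5 h could not be among the 144. Some of them were called higher at 91 h, such as Psmb9 (3.75), Gbp9 (3.17), Zbp1 (2.96) and Psmb8 (2.74), while others, such as Ciita, had no ratio at 91 h. The shares from 23.5 h therefore describe only genes listed for both groups at that time.

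Mock was compared with T0 to describe change without added IFNγ. Time in culture cannot be told apart there from detachment, the medium pulse, washing and seeding, which T0 cells may not have been through. At 23.5 h the interferon genes of the mock group were little above T0. The GTPase list had a median log2 ratio of 0.42 (0 of 7 past the rule of size with the authors' adjusted p under 0.05). The type 1 interferon-stimulated list had a median of 0.32 (0 of 42 past the same rules), at percentile 100 of the random lists of matched level. At 48 h 42 of 44 were higher (median 3.06) and at 91 h 40 of 44 (median 2.98). From the authors' p adjusted over the list alone, at any fold, the counts were 12, 44 and 43. Isg15, a ubiquitin-like antiviral protein gene, went from 135 normalised reads in T0 to 167, 2383 and 4571 in mock. GTPase genes were higher in 12 of 12 at 48 h (median 3.65) and 11 of 11 at 91 h (median 3.53), with 12 and 11 adjusted over the list alone. Class I genes were higher in 15 of 23 (median 1.78) and 13 of 22 (median 1.33) with 1 lower at each time, and in 20 and 18, with 3 and 2 lower, adjusted over the list alone. Markers of other cells moved too. Lck went from 25.5 in T0 to 120 at 48 h (2.20) and 130 at 91 h (2.31), past both rules, as was the myeloid marker Lyz2 at 48 h (1.53), and Vwf stood at 0.87 and -0.50. Of 6 fibroblast genes 1 was lower at 48 h and 2 at 91 h (3 lower and 1 higher, then 2 lower, adjusted over the list alone), Col1a2 by 2.43 and 2.19 and Pdgfra by 3.11 at 91 h. These list counts use the authors' deposited table for p, and camera's smallest adjusted p over all lists was 0.482, 0.408 and 0.258 with an estimated correlation at the 3 times.

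Control genes of housekeeping function were themselves lower in mock than in T0, with medians of -0.37 at 48 h and -0.40 at 91 h. By size and the authors' adjusted p 1 of 16 was higher and 1 lower at 48 h, and 1 higher and 2 lower at 91 h. Adjusted over the list alone at any fold, 2 were higher and 8 lower at 48 h and 3 and 13 at 91 h (adjusted p = 0.408 and 0.258 with an estimated correlation). Division genes were lower by more at 91 h. In mock at 91 h all 30 G2/M genes (median -5.22) and all 28 S phase genes (median -3.33) were lower than T0, where at 48 h 0 and 19 had been (medians -0.50 and -1.22). Adjusted over the list alone at any fold, 25 and 28 were lower at 48 h and 30 and 28 at 91 h. Mki67 went from 13349 in T0 to 295 with mock and 183 with IFNγ, and Ccnb1, the mitotic cyclin, from 2912 to 115 and 95.4. Stress response genes were higher in 15 of 27 at both 48 h (median 1.07, 2 lower) and 91 h (median 1.21, 3 lower), and in 19 adjusted over the list alone at each, where 7 and 6 were lower, with Ddit3, which encodes CHOP, at 535 in T0 and 784, 5342 and 13025 in mock. At 91 h 13 of 20 p53 targets were higher and 1 lower (18 and 1 adjusted over the list alone, median 1.13) and 18 of 24 sterol genes lower (24 adjusted over the list alone, median -1.15). Of 30 hypoxia genes 9 were lower and 2 higher (20 and 6 adjusted over the list alone, median -0.83). NF-κB targets were higher in 7 of 11 at 48 h (9 and 1 lower adjusted over the list alone, median 1.51) and chemokines in 7 of 12 with 1 lower (9 and 1 adjusted over the list alone, median 1.08).

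In mock, 12 genes were higher and 8 lower than T0 by the rule of size at all 3 times. Ifi44 went from 8.37 to 22.5, 575 and 1129 normalised reads (6.91 at 91 h), and in the authors' deposited table its adjusted p was 0.388 at 23.5 h and 1.3e-242 at 91 h. Kcnj13 (6.24), Trib3 (4.33), Gbx1 (3.49), the retinoid reductase gene Dhrs3 (3.08), Chac1 (2.87), Rarb (2.20), a retinoic acid receptor gene, and Tmem255a (1.79) followed at 91 h. On the lower side were Adcy1 (-4.03), Cyp26b1 (-1.55), which degrades retinoic acid, Lat2 (-1.10, not past the authors' deposited table's threshold at 91 h, with their adjusted p = 0.141) and Ighm, from 23.1 to a value listed at 0. At 23.5 h the authors' deposited table did not pass Kcnj13 (their adjusted p = 0.230), Gbx1 (0.372), Tmem255a (0.291, and 0.112 at 48 h), Ighm (0.113) and Lat2 (0.352) either.

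By the authors' deposited table, adjusted p under 0.05, mock had 480 genes higher and 249 lower than T0 at 23.5 h, 3381 and 3303 at 48 h and 3927 and 3935 at 91 h. In the same authors' deposited table, IFNγ had 1496 and 1081, then 3217 and 2847, then 4165 and 4003. By the rule of size the mock counts were 28 and 29, 986 and 464, and 1145 and 1388, and those with IFNγ 265 and 99, 1112 and 448, and 1267 and 1397. All these comparisons share the T0 libraries. By the rule of size, mock at 23.5 h had 75 higher genes without T0 library 1, 44 higher and 47 lower without its own library 2 and 51 lower without its library 1. IFNγ had 153 lower genes at 23.5 h and 776 at 48 h without its own library 2 of that time.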

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

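The comparison between times was planned as a difference in size. Its limma test was added once the libraries had been recovered, and the tests of explanations were chosen after the result was seen.

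The IFNγ to mock ratio differed between 23.5 and 91 h in limma's interaction test for 493 genes with a higher and 670 with a lower ratio at 91 h, of 12515 tested. By the rule of size and limma together the counts were 57 and 125. Without a variance trend limma counted 112 and 233 (20 higher with the rule of size), and in 1 fit over all 14 libraries 32 and 108 (12 and 80 with it). Of the genes whose ratio fell most, Igtp differed by -5.22 (log2, 91 h minus 23.5 h), Iigp1 by -4.86, Apol9a by -4.68, C4b by -4.51, Nlrc5 by -4.22, Apol9b by -4.08, Irgm2 by -3.89 and Gbp3 by -3.75. The fixed genes gave -3.74 for Gbp2, -3.32 for Tap1, -3.06 for Irgm1, -1.76 for Irf1, -1.51 for B2m, -1.50 for Socs1, -1.41 for H2-K1, -1.19 for H2-D1, -1.11 for Cd274 and -0.55 for Cxcl10, where limma's adjusted p ran from 1.6e-13 (Igtp) to 0.0129 (Socs1). From 23.5 to 91 h the mock level rose in all the genes just named except Cxcl10 (Apol9a from 17.7 to 665). With IFNγ the level itself also rose for Apol9a (1937 to 2693), C4b (1130 to 2285), Apol9b, B2m, H2-K1, H2-D1 and Cd274. It fell for Igtp (6304 to 1846), Iigp1, Nlrc5, Irgm2, Gbp3, Gbp2, Tap1, Irgm1, Irf1, Socs1 and Cxcl10. Ratios higher at 91 h were those of Aire by 2.21 (limma adjusted p = 0.0087), the pseudogene Mnd1-ps by 2.19 (limma adjusted p = 0.0393, at 6.44 and 1.25 normalised reads with IFNγ and mock at 91 h), Ankrd37 by 2.17 (limma adjusted p = 0.0040) and Rny3 by 2.12 (limma adjusted p = 0.0085). Between 23.5 and 91 h Aire went from 130 to 313 with IFNγ and from 142 to 73.2 with mock, against 257 in T0. Ccdc74a, at 1.40 with mock at 91 h, differed by 2.69 without passing (limma adjusted p = 0.0502). The histone genes Hist3h2bb-ps (2.32), Hist1h2bh (2.25) and Hist1h3g (2.17), under 3 normalised reads in both groups at 91 h, were not tested. Class I presentation genes had a median difference of -1.84, with 15 of 20 lower by both rules, and this was the list that passed camera with an estimated correlation (adjusted p = 0.0225). GTPase genes stood at -3.74 (8 of 8 lower) and type 1 interferon-stimulated genes at -2.06 (36 of 42 lower), each with adjusted p = 0.055 with an estimated correlation. Without IFNγ library 1 of 23.5 h limma counted 222 and 358, without library 2 of that group 245 and 360, without IFNγ library 1 of 91 h 264 with a higher ratio, and without mock library 1 of 23.5 h 318. With the rule of size as well the 57 larger ratios became 28 without IFNγ library 1 of 23.5 h, 24 without mock library 1 of 23.5 h and 27 without IFNγ library 1 of 91 h.

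Type 1 interferon-stimulated genes were higher in the mock group at 48 and 91 h than in T0. RNA of IFNγ libraries mixed into the mock libraries would raise the GTPase list at least as much, as a share of the IFNγ level, as the type 1 list. The mock level was 18.5% of the IFNγ level in the GTPase list (quartiles 8.34% to 25.7%) and 61.8% in the type 1 list (47.3% to 73.9%) at 48 h, and 35.9% (22.9% to 48.4%) and 76.5% (67.2% to 85.3%) at 91 h, which argues against that source as the whole cause at both times. A small amount of IFNγ reaching the mock wells stays open, since the GTPase list was itself higher in mock than in T0 by a median of 3.65 at 48 h. An interferon response of the cells to their own state after days in culture, a biological hypothesis, also stays open, because time and crowding were not varied apart from each other.

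At 48 h the IFNγ libraries differed from each other by 2-fold in genes of high level. If library 1 were a mix of library 2 and mock RNA, its levels would lie between those of both, but in 37.1% of 116 genes (49 higher in library 1, 67 in library 2) they lay outside that interval, which argues against mixing as the whole cause. Within the GTPase and antigen presentation lists the implied share of library 2 was 32.6% (quartiles 22.3% to 45.8%, 31 genes), a spread that decides nothing under a bound set after the values were seen. A mock library under a wrong label is argued against by the GTPase list, which stood 1.81 above the mock mean in library 1 (quartiles 1.39 to 2.86). Over genes of high level library 1 lay nearer the 48 h mock mean (SD of the log2 ratio 0.212) than library 2 did (0.380). Of the other groups, library 2 lay nearest the mean of IFNγ at 23.5 h (0.365, against 0.518 for library 1). The explanations above all take library 1 as the deviating one, and whether library 2 deviated was not tested. A difference between the wells in dose or handling, which may have caused these gaps, was not tested either.

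Hypoxia and glycolysis genes were higher with IFNγ than with mock at 91 h. With equal totals of recovered genes in place of the T0 scale the median of the list was 0.71 (quartiles 0.26 to 0.92), with totals of all listed genes 0.75, and the smallest of the medians of the 4 pairs of an IFNγ and a mock library was 0.58 (highest 0.88), so neither the scale nor a single library accounts for it. Between IFNγ libraries 1 and 2 of 48 h the list differed about as much, by a median of 0.72 (library 2 over 1, quartiles 0.43 to 0.93; Bnip3 2496 and 5983, Pdk1 3124 and 5218, Car9 2152 and 1954), but library 2 also held more Iigp1 (4888 and 14319), so this gap does not separate culture from the response to IFNγ. At 91 h the list was near T0 with IFNγ (median 0.08) and below it with mock (-0.83). A difference in cell number, medium or oxygen between wells could give the pattern and was not tested, and a lasting effect of the pulse is a hypothesis beside it.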

How the results depend on the processing

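The fit over all 14 libraries, the fit without a variance trend and the removal of single libraries from results other than gene counts were chosen after seeing the data, and the other alternatives before. Of 542 alternative values for the 50 leading results 380 stayed within 1.5 times the value reported or on their side of the threshold and 162 did not. Of 132 for 12 further counts 97 did and 35 did not. With equal totals of recovered genes the majority by limma turned from higher to lower at 23.5 h (902 and 1004) and at 91 h (945 and 1083). The log2 of the IFNγ total over the mock total was 0.02, 0.04 and 0.02 over recovered genes at 23.5, 48 and 91 h, so that equal totals lowered every IFNγ to mock ratio. Over all listed genes it was -0.04, -0.02 and -0.02, so that equal totals would raise them. Where no cause is given below, the cause was not tested. No paired analysis was possible because the columns carry no replicate numbers and the numbering of the recovered libraries is arbitrary. A fit with a replicate block was therefore not run. A count tool was not run either, because the deposited values are means and not reads, and it was not tried on the reads recovered from them.

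For IFNγ against mock, counts are given as higher and lower, at 23.5, 48 and 91 h in turn. With T0 as the reference in place of mock, another question, the rule of size took 265 and 99, 1112 and 448, 1267 and 1397. With limma as well it took 254 and 99, 861 and 372, 1238 and 1382, and limma alone 2503 and 2255, 1724 and 1665, 4850 and 4777. With the mean of the 3 mock groups as the reference, whose spread then holds the change over time, the rule of size took 315 lower at 23.5 h, 38 at 48 h and 752 at 91 h, and limma 11 and 0 at 23.5 h and 0 and 0 at 91 h, with and without the rule of size. One fit over all 14 libraries, which lends the spread of the 48 h libraries to all, gave 242 and 77, 416 and 264, 92 and 67 by limma. With the rule of size it gave 12 lower at 23.5 h, 88 and 33 at 48 h, and 29 and 5 at 91 h. Without a variance trend limma gave 295 and 85 at 23.5 h and 71 and 36 at 91 h, with the rule of size 12 lower and then 41 and 7. The exact binomial test, which compares libraries, passed 2341 and 2280, 3155 and 3155, 2413 and 2226, and with the rule of size 169 and 67 at 48 h. At 1.5-fold the rule of size took 291 and 209, 558 and 270, 293 and 217, with limma 236 and 119 at 23.5 h and 193 and 114 at 91 h. At 4-fold it took 76 and 1, 45 and 0, 15 and 1, with limma 76 and 1 at 23.5 h and 15 and 0 at 91 h. With a level of at least 100 the lower genes numbered 19, 36 and 5, with limma 18 at 23.5 h and 5 at 91 h. Without a minimum of level they numbered 57 at 91 h, and with a pseudocount of 5 they numbered 17 there, 15 with limma.

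The share of genes higher at 23.5 h that were past the rule at 48 and 91 h was 57.8% and 23.9% at 1.5-fold and 27.6% and 7.89% at 4-fold, and 25.6% at 91 h for genes selected at 48 h. For the difference between times, counts are given as larger and smaller ratio at 91 h. At 1.5-fold they were 427 and 439 by size and 133 and 238 with limma, at 4-fold 10 and 57 by size and 5 and 56 with limma, and with a level of at least 100 the larger ones were 41 by size and 35 with limma. Without a variance trend limma alone gave 112 and 233, and 20 larger with the rule of size. One fit over all 14 libraries gave 32 and 108, and 12 and 80 with the rule of size. Against T0, by the rule of size alone in place of the authors' adjusted p, IFNγ had 265 and 99, 1112 and 448, 1267 and 1397, and mock 28 and 29, 986 and 464, 1145 and 1388. A threshold of 0.01 on the authors' adjusted p left 307 and 151 for mock at 23.5 h.

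Leaving out each library in turn gave the following ranges, where a lone library is assumed to vary as the others do. At 23.5 h the rule of size took 154 to 176 higher and 33 to 116 lower, with limma 138 to 157 and 23 to 89, and limma alone 602 to 1177 and 398 to 971. At 48 h these were 134 to 390 and 77 to 245, 4 to 346 and 0 to 237, and 4 to 1663 and 0 to 1622. There IFNγ library 1 gave the highest values when left out, 346 and 237 with both rules, and library 2 gave 80 and 44. At 91 h they were 82 to 109 and 63 to 73, 54 to 105 and 18 to 45, and 497 to 1042 and 421 to 921. Shares past the rule ran from 29.1% (without IFNγ library 2 of 48 h) to 56.2% at 48 h and from 13.3% to 17.4% at 91 h. For the difference between times, larger ratios ran from 101 to 178 by size, 24 to 71 with limma and 222 to 440 by limma alone. The smaller ones ran from 170 to 202, 117 to 132 and 358 to 654. Lists in the upper and lower tails of the random lists numbered 10 to 13 and 5 to 7 at 23.5 h, 8 (without IFNγ library 2) to 14 and 4 to 7 at 48 h, and 8 to 9 and 4 (without IFNγ library 2) to 7 at 91 h for IFNγ against mock. For mock against T0 they numbered 6 to 9 and 3 to 6, 12 to 12 and 4 to 5, and 10 to 11 and 5 to 5. Depth limits what is said of genes near the minimum level of 20, such as Prr7 and Cpz.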

Other observations

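The tests in this part are descriptions, and the groups were picked from the lists after the result was seen. The type 1 interferon-stimulated gene Isg15 stood at 1975 with IFNγ and 167 with mock at 23.5 h, at 4278 and 2383 at 48 h, and at 4999 and 4571 at 91 h. Ifit1, whose product binds viral RNA, went from 417 normalised reads in T0 to 425, 4812 and 5826 in mock. Nlrc5 in mock reached 155 at 91 h, and H2-K1 2550, against 846 and 14188 with IFNγ. The median IFNγ to mock ratio at 91 h was 0.38 for type 1 interferon-stimulated genes and 1.48 for GTPase genes, and the difference between these lists was not tested.

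Of the 70 genes called higher at 91 h, 49 were not called at 23.5 h, 33 of them listed for both groups at that time. Among them were Ankrd37, Car9, Bnip3, Adm, Pdk1 and Tpi1 of the hypoxia and glycolysis list, with the lactate exporter gene Slc16a3 (1.24) and the phosphofructokinase gene Pfkl (1.16) beside them, chosen after their values were seen. The lactate dehydrogenase gene Ldha stood at 17522 with IFNγ and 8837 with mock (0.99, limma adjusted p = 4.4e-07) and the glucose transporter gene Slc2a1 at 2955 and 1567 (0.91, limma adjusted p = 3.8e-07). The list was lower in mock at 91 h than in T0, with a median of -0.83. For the difference between times its median was 0.72, with 5 of 30 genes larger by both rules (adjusted p = 0.253 with an estimated correlation).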
